A study of Homo sapiens with 6 samples.

How the data were processed

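Expression was measured on 6 Affymetrix arrays of SNU-449, a human hepatocellular carcinoma cell line. Per the labels, 3 arrays held RNA of cells transduced with an empty vector and 3 held RNA of cells stably transduced with a lentivirus carrying USP48, a ubiquitin-specific protease, after selection with puromycin. The group and the replicate number of each array were taken from its title, which calls the cells transfected with vector or with USP48. The difference between that wording and stable transduction was not resolved here. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

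The deposited values are on a log2 scale, 1 value per probe set and array, and were made with RMA per the submitters' processing notes. The RMA version and settings are not given in the sources used here. The values ran from 0.190 to 13.2, and the medians of the arrays from 3.75 to 3.79. Values below 1 are lower than RMA usually gives, so another background correction may have been used, which would change what dim values and large log2 differences mean. They are called RMA values here by those notes alone. RMA equalises the distribution of signal between arrays, so a change of total RNA per cell cannot be seen in such values. No detection calls were used, and for arrays it can be said only that their number, 3 per group, limits the precision. No 2 columns were identical, and 0 columns of the table were left unused.

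Of 54675 probe sets, 62 were controls, 41091 named 1 gene symbol in the platform annotation, 1801 named several and 11721 named none. Of those with 1 symbol, 41037 matched a RefSeq table of GRCh38.p14, used for names only, and 0 symbols changed. Each gene was represented by the probe set with the highest mean over all 6 arrays, which gave 19775 genes. Of these, 10523 had several probe sets, and 585 had probe sets called in opposite directions. No filter on dim probe sets and no further normalization was applied. No coordinates are given, because the positions of the probe sets were not analysed here.

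Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes, threshold 0.05), with a size limit of 2-fold as a second count. Differences are log2 values of the arrays labelled USP48 overexpression minus those labelled empty vector. Single measures were compared with a two-sided exact permutation test, whose smallest p for 3 against 3 arrays is 0.1. For 39 gene lists the camera test of limma was run with a preset correlation of 0.01 between genes and adjusted over the 39 lists, and members past the gene test were counted after adjustment over all genes and adjusted over the list alone. Members with no probe set naming that gene alone were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

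The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a later choice is named. The named genes are USP48, then the 12 genes with the highest and the 12 with the lowest log2 difference among those past the threshold whose groups do not overlap and whose higher mean lies above the median of all genes, leaving out symbols of uncharacterised or small RNA genes (starting with LOC, LINC, MIR, SNORD or SNORA, or containing orf). For each list up to 4 members past the threshold with the largest absolute difference are named, or 2 members where none passed. The alternatives were quantile normalization, median centring, an intensity trend with a robust prior, leaving out the dimmest 33.3% of genes by mean, the mean of all probe sets of a gene, every probe set on its own, the replicate number as a block, each of the 6 arrays left out in turn, an adjusted p under 0.01, a limit of 1.5-fold, camera on ranks and camera with an estimated correlation. Scaling the arrays on the hybridization controls, which are labelled RNAs added before hybridization, was an alternative chosen after seeing the data. A trend with gene length and a set of ubiquitin-specific proteases picked by their values were also looked at after seeing the data and are not reported.

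The test was checked on simulated data with the means and spread of these 19775 genes, of which 200 were changed. It recovered 90% of genes changed by 1 on the log2 scale and 41% of those changed by 0.5, 100% of them with the right sign, and called 9 unchanged genes. With no change simulated, 0 genes were called. The share recovered at an adjusted threshold depends on how many genes change, and 5897 were called in the real data. The 90% and 41% therefore do not give the recovery in these data. Of simulated lists of 20 genes, 100% of those shifted by 0.5 and 4% of the unshifted ones had an unadjusted camera p under 0.05. The simulated genes were independent, while the estimated correlation between genes was 0.65 in the type I interferon list. The 4% therefore does not give the rate of false calls for lists of correlated genes.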

Results

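Gene expression was compared between SNU-449 hepatocellular carcinoma cells labelled as stably overexpressing USP48 and cells labelled as carrying the empty vector, with 3 arrays in each group. The question set by the labels is which transcripts differ between the 2 groups. Over 19775 genes, Pearson correlations across genes between arrays were 0.9974 to 0.9976 within the empty vector group, 0.9957 to 0.9969 within the USP48 group and 0.9821 to 0.9859 between groups, and the first principal component held 77.73% of the variance and separated the groups. Genes are not independent replicates in these correlations.

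Control probe sets also differed between the groups. The 18 hybridization control probe sets averaged 9.79 ± 0.04 (SD, n = 3) in the empty vector arrays and 10.09 ± 0.10 (SD, n = 3) in the arrays labelled USP48 overexpression on the log2 scale (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow), and 18 of 18 were higher in every USP48-labelled array. The 24 poly-A control probe sets averaged 5.13 ± 0.13 and 5.55 ± 0.24 (SD, n = 3 each; exact permutation p = 0.1). The difference between the 5′ and the 3′ probe set of GAPDH, a measure of RNA integrity, was −0.38 ± 0.06 in the empty vector arrays and −0.76 ± 0.48 in the USP48-labelled arrays (SD, n = 3 each; exact permutation p = 0.1). USP48 overexpression replicate 3 was at −1.31, and the other USP48-labelled arrays were at −0.51 and −0.45. For ACTB the difference was −3.46 ± 0.22 and −3.82 ± 0.35 (SD, n = 3 each; exact permutation p = 0.2).

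USP48 itself was not called higher in the arrays labelled USP48 overexpression by any of its probe sets. Of its 5 probe sets, 220079_s_at fell from 7.88 ± 0.05 to 7.06 ± 0.12 (SD, n = 3 each), a log2 difference of −0.82 with a standard error of 0.10 and a limma adjusted p of 0.00013 over all probe sets. Probe set 220078_at fell by 0.63 on the log2 scale (limma adjusted p = 0.00085). The remaining probe sets did not pass the test, with log2 differences of −0.13 for 225925_s_at, 0.24 for 229812_at and −0.25 for 232621_at and adjusted p of 0.37, 0.12 and 0.22. At the level of genes, where 225925_s_at is the brightest probe set, the difference was −0.13 (limma adjusted p = 0.305). With the mean of all probe sets it was −0.32 (adjusted p = 0.0071), and with arrays scaled on the hybridization controls, chosen after seeing the data, −0.42 (adjusted p = 0.0049). Where the probe sets lie relative to the transferred sequence is not known here, so these values do not test for the transgene. The groups are therefore named by their labels throughout.

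**Figure D1:**
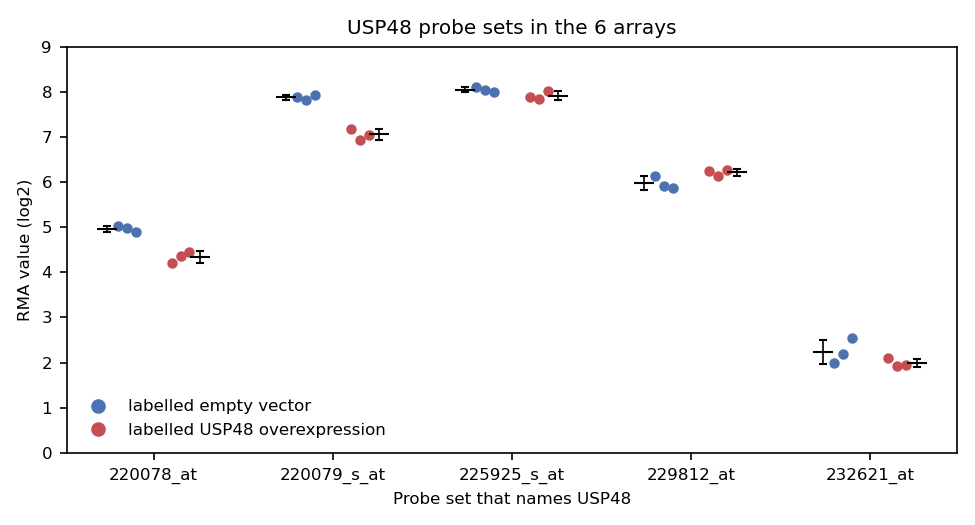
RMA values (log2, y axis) of the 5 probe sets that name USP48 (x axis) in the 3 arrays labelled empty vector and the 3 arrays labelled USP48 overexpression, each point 1 array, with the mean and SD of each group as black marks. Probe sets 220079_s_at and 220078_at were lower in the USP48-labelled arrays by 0.82 and 0.63 on average, and no probe set passed the test in the other direction.

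Between the groups, 5897 of 19775 genes (29.8%) changed at a limma adjusted p under 0.05, of which 3103 were higher and 2794 lower in the arrays labelled USP48 overexpression, in which USP48 was not called higher. At least 2-fold changes were found for 739 genes, 362 higher and 377 lower, and at least 4-fold changes for 80 higher and 18 lower genes. The groups did not overlap for 8489 genes (42.9%, against 10% by chance for 3 against 3 arrays). The balance of directions depends on the scaling. As deposited, 52.6% of changed genes were higher and the median log2 difference of all genes was 0.05. With arrays scaled on the hybridization controls 8452 genes changed, 957 higher and 7495 lower (11.3% higher), and the median of all genes was −0.24. Of those 8452 genes, 1023 changed at least 2-fold, 192 higher and 831 lower. That scaling lowers every log2 difference by 0.294. With the mean of all probe sets of a gene, 427 genes changed at least 2-fold, 259 higher and 168 lower.

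The 12 highest and 12 lowest genes are those of the naming rule, which asks for groups that do not overlap and a higher mean above the median of all genes. CXCL8, a neutrophil chemokine, rose from 2.89 ± 0.13 to 8.39 ± 0.76 (SD, n = 3 each), with a log2 difference of 5.50 (SE 0.29, limma adjusted p = 7.6e-07), while its other probe set was at 1.60. IL6, an inflammatory cytokine, rose from 4.80 ± 0.07 to 9.61 ± 0.06, 28.0-fold, with a log2 difference of 4.81 (SE 0.08, limma adjusted p = 4.5e-10). They were followed by RSAD2 at 4.65, the RNA sensor RIGI at 4.40, the chemokines CXCL11 at 4.28 and CCL5 at 4.23, MX2 at 3.85, IFI44L at 3.70, XAF1 at 3.67, PHLDA1 at 3.63, IFI27 at 3.62 and the death ligand TNFSF10 at 3.60 on the log2 scale. The empty vector means of CXCL8, RSAD2 (3.21), CXCL11 (2.16), XAF1 (3.73) and TNFSF10 (2.14) lay below the median of every array. Detection against background was not analysed here, so their differences and ranks are those of RMA values and no fold is given. Of the 151 named genes past the threshold, here and below, 17 had a group mean below the median of every array, 2 of them in both groups. The lowest were NEURL1B (log2 difference −2.66, 6.31-fold lower, SE 0.18, limma adjusted p = 3.0e-06), REEP1 at −2.59, the spindle protein ASPM at −2.55, BRI3BP at −2.52, MBNL3 at −2.42, QSER1 at −2.36, IFT80 at −2.33, MEOX1 at −2.22, NT5DC2 at −2.18, ABLIM1 at −2.16, EEIG2 at −2.14 and GET1 at −2.12. All 3 arrays of one group lay beyond all 3 of the other for each of these 24 genes, as the rule for naming requires. Probe sets of one gene did not always move together: another probe set was at 0.65 for XAF1 and PHLDA1, 1.71 for TNFSF10, −0.78 for ASPM, −1.25 for ABLIM1, −0.04 for RIGI, −0.06 for MBNL3, −0.01 for QSER1, −0.05 for NT5DC2 and 0.31 for IFT80. Of the 99 named genes past the threshold, here and below, that have several probe sets, 69 had one whose difference was smaller than the printed one by more than 1.5 times or in the other direction, 24 of them in the other direction.

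**Figure D2:**
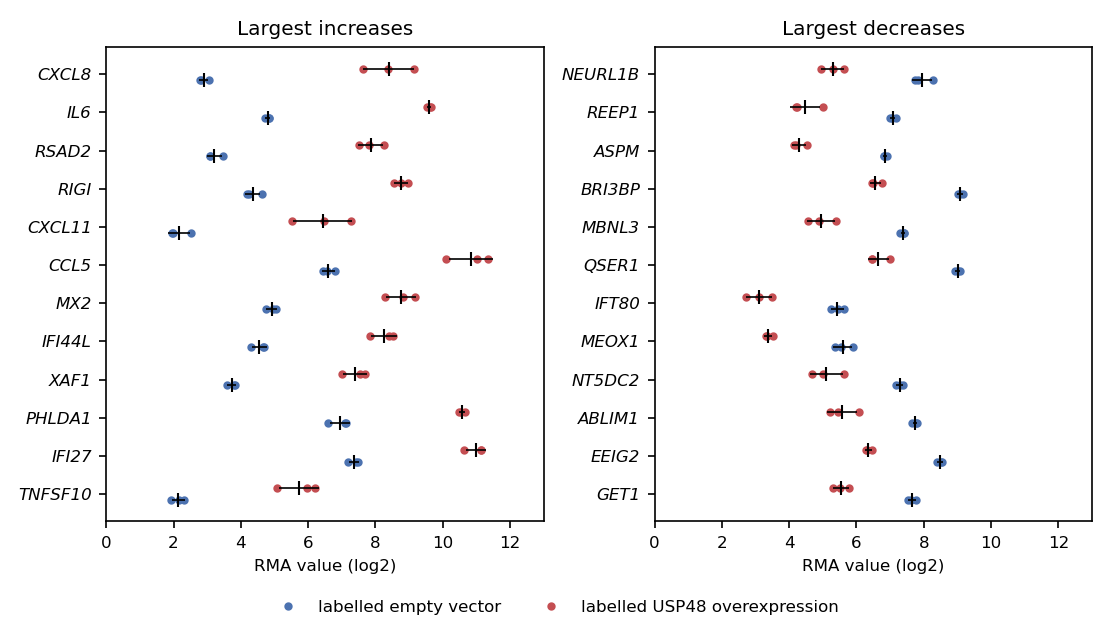
RMA values (log2, x axis) of the 12 highest (left) and the 12 lowest genes (right) by the naming rule, each point 1 array, with black bars for the mean and SD of the 3 arrays labelled empty vector and the 3 labelled USP48 overexpression. CXCL8 moved from 2.89 to 8.39 and NEURL1B from 7.95 to 5.29, and in every gene shown the groups do not overlap. USP48 itself was not called higher in the arrays so labelled.

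Interferon-induced genes rose as a group in the USP48-labelled arrays, in which no USP48 probe set was called higher. Of 31 measured members of the type I interferon list, 30 rose and 0 fell (30 and 0 adjusted over the list alone), with a median log2 difference of 2.20 and a camera adjusted p of 2.6e-26 (adjusted p = 0.23 with an estimated correlation). RSAD2, RIGI, MX2 and IFI44L had the largest increases, and CMPK2, picked after its value was seen as the 1 member that did not pass, was at −0.02. With arrays scaled on the hybridization controls the median was 1.90, with 27 members higher and 1 lower, and without USP48 overexpression replicate 3 it was 2.37. Genes of MHC class I presentation, which loads peptides for T cells, rose in 12 of 16 cases and fell in 0 (13 and 1 adjusted over the list alone; median 0.81, camera adjusted p = 5.4e-06, adjusted p = 0.33 with an estimated correlation). The peptide transporters TAP1 and TAP2 rose by 1.36 and 0.92, HLA-E by 1.12 and NLRC5, a regulator of these genes, by 0.93. The median of this list was 0.51 after scaling on the hybridization controls.

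Inflammatory genes moved the same way. Of 25 NF-κB and inflammatory cytokine targets, 21 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 1.40 and a camera adjusted p of 2.9e-17 (adjusted p = 0.173 with an estimated correlation). CXCL8 and IL6 were followed by CXCL2 at 3.34 and IL1A at 3.10, which had other probe sets at 0.08 and −0.04. After scaling on the hybridization controls the median was 1.10, with 18 members higher and 1 lower, and without USP48 overexpression replicate 3 it was 1.39, with 20 members higher. Of 16 pyroptosis and inflammasome genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.31, camera adjusted p = 0.00057, adjusted p = 0.23 with an estimated correlation). Those with the largest increases were the DNA sensor AIM2 at 3.51, IL1B at 1.20, the inflammatory caspase CASP4 at 1.19 and IL18 at 0.65. That median was 0.02 after scaling on the hybridization controls, where IL18 no longer passed (0.36, adjusted p = 0.062). Of 14 leukocyte markers, 1 rose and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.342). The 1 marker, CD2, was at 0.29 (limma adjusted p = 0.036), at −0.01 after scaling on the hybridization controls, and lost its call without any 1 of the 5 arrays other than USP48 overexpression replicate 3 (adjusted p = 0.139 without empty vector replicate 2), after quantile normalization (adjusted p = 0.111) and with an intensity trend and robust prior (adjusted p = 0.051). USP48 was not called higher in the arrays from which these directions are drawn.

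The immediate early, MAPK feedback, integrated stress response and YAP/TAZ lists were also called higher in the USP48-labelled arrays, without a called rise of USP48. Of 18 immediate early genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.99, camera adjusted p = 2.9e-11, adjusted p = 0.064 with an estimated correlation), among them the transcription factors ATF3 at 2.43, EGR1 at 2.27, KLF4 at 1.67 and KLF6 at 1.49. Of 16 MAPK feedback targets, 12 rose and 0 fell (13 and 0 adjusted over the list alone; median 1.35, camera adjusted p = 8.3e-10, adjusted p = 0.275 with an estimated correlation). PHLDA1 led them at 3.63, with the MAPK phosphatases DUSP5 at 2.94 and DUSP6 at 2.93 and the AP-1 subunit FOSL1 at 2.50. In the integrated stress response list 15 of 23 genes rose and 1 fell (16 and 3 adjusted over the list alone; median 0.59, camera adjusted p = 7.0e-07, adjusted p = 0.33 with an estimated correlation), and STC2 at 2.82, DDIT3 at 2.79, CHAC1 at 2.76 and PPP1R15A at 2.61 changed most. Its median was 0.29 after scaling on the hybridization controls, with 11 members higher and 4 lower. Of 21 YAP/TAZ targets, 10 rose and 3 fell (12 and 3 adjusted over the list alone; median 0.30, camera adjusted p = 0.00025, adjusted p = 0.173 with an estimated correlation). The matricellular genes CCN2 at 2.64 and CCN1 at 2.22, GADD45A at 2.29 and the coagulation initiator F3 at 2.10 had the largest increases. The median of the list was 0.01 after scaling on the hybridization controls.

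Genes of mitosis fell, and those of DNA replication fell in part, in the same arrays, which showed no called rise of USP48. All 31 measured mitosis and G2/M genes fell (31 adjusted over the list alone), with a median log2 difference of −1.03 and a camera adjusted p of 3.6e-25 (adjusted p = 0.195 with an estimated correlation). ASPM was followed by the kinetochore protein CENPF at −2.08, the topoisomerase TOP2A at −1.89 and the cytokinesis protein ANLN at −1.62. All 31 were also lower after scaling on the hybridization controls (median −1.33) and without USP48 overexpression replicate 3 (median −1.03). The number was 30 with the mean of all probe sets and without empty vector replicate 1 or 2 or USP48 overexpression replicate 1 or 2. Of 31 DNA replication and G1/S genes, 1 rose and 16 fell (1 and 21 adjusted over the list alone; median −0.36, camera adjusted p = 5.2e-08, adjusted p = 0.195 with an estimated correlation), with POLA1 at −0.78, MCM5 and GINS1 at −0.73 and RFC3 at −0.66. RFC3 did not pass with the mean of its probe sets (−0.22, adjusted p = 0.054). The median of the list was −0.65 after scaling on the hybridization controls. Of 16 homologous recombination and Fanconi genes, 1 rose and 8 fell (4 and 8 adjusted over the list alone; median −0.26, camera adjusted p = 0.0193, adjusted p = 0.23 with an estimated correlation). EXO1 at −0.95, BLM and RAD54L at −0.68 and BRCA1 at −0.60 changed most. The list did not pass after quantile normalization (adjusted p = 0.060), without the dimmest 33.3% of genes (adjusted p = 0.090) or on ranks (adjusted p = 0.071). Its median was −0.55 after scaling on the hybridization controls. Of 16 replication-dependent histone genes, 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.797; median 0.09, −0.20 after scaling on the hybridization controls), with H2AC6 at 0.78, H1-5 at −0.62, H2BC5 at 0.59 and H4C8 at 0.53. H2AC6 did not pass without empty vector replicate 3 (adjusted p = 0.064) or USP48 overexpression replicate 1 or 2. H4C8 did not pass without any 1 of the 5 arrays other than empty vector replicate 1 (adjusted p = 0.165 without empty vector replicate 2), after quantile normalization (adjusted p = 0.087) or after median centring (adjusted p = 0.054). Scaling on the hybridization controls ended the calls of H2AC6, H2BC5 and H4C8 (adjusted p = 0.071, 0.104 and 0.286).

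Genes of lipid synthesis fell in the USP48-labelled arrays, again with no called rise of USP48. Of 18 cholesterol synthesis genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone; median −0.56, camera adjusted p = 1.8e-08, adjusted p = 0.23 with an estimated correlation), with SQLE, which epoxidises squalene, at −1.06, IDI1 at −0.84, DHCR7 at −0.83 and EBP at −0.73. Of 15 fatty acid synthesis genes, 0 rose and 11 fell (1 and 11 adjusted over the list alone; median −0.49, camera adjusted p = 7.6e-06, adjusted p = 0.23 with an estimated correlation). The desaturase SCD was at −2.08, ACACA at −1.25, FASN at −1.11 and ACSL1 at −0.95, and a dimmer FASN probe set was at 0.06. Of 33 oxidative phosphorylation genes, 1 rose and 8 fell (2 and 13 adjusted over the list alone; median −0.12, camera adjusted p = 0.0118, adjusted p = 0.54 with an estimated correlation), with ATP5PB at −0.50, UQCRC1 at −0.45 and NDUFV1 and ATP5F1A at −0.42. That list did not pass without the dimmest 33.3% of genes (adjusted p = 0.079), and NDUFV1 and ATP5F1A did not pass with the mean of their probe sets (adjusted p = 0.137 and 0.067). The medians of the cholesterol, fatty acid and oxidative phosphorylation lists were −0.86, −0.79 and −0.41 after scaling on the hybridization controls.

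Heat shock, proteasome and hypoxia lists were also called, in arrays in which USP48 was not called higher. Of 15 heat shock genes, 1 rose and 7 fell (1 and 7 adjusted over the list alone; median −0.31, camera adjusted p = 0.0060, adjusted p = 0.38 with an estimated correlation). The chaperone genes DNAJB1, HSPB1 and HSPH1 were at −0.59, −0.54 and −0.51, and CRYAB at 0.57. The median was −0.60 after scaling on the hybridization controls, where CRYAB no longer passed (0.28, adjusted p = 0.066). Of 27 proteasome genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 0.0418, adjusted p = 0.68 with an estimated correlation), with PSMB7 at 0.54, PSMD6 at 0.43, PSMA2 at 0.40 and PSMC4 at 0.39. The proteasome median turned to −0.13 after scaling on the hybridization controls (adjusted p = 0.18), and the call was lost without empty vector replicate 2 (adjusted p = 0.091), empty vector replicate 3 (adjusted p = 0.198) or USP48 overexpression replicate 2 (adjusted p = 0.089). It was also lost with the mean of all probe sets (median 0.09, adjusted p = 0.742) and after quantile normalization (adjusted p = 0.0547). With the mean of all probe sets PSMD6 and PSMA2 did not pass (adjusted p = 0.414 and 0.483) and PSMB7 was at −0.26 (adjusted p = 0.072). After scaling on the hybridization controls PSMB7, PSMD6, PSMA2 and PSMC4 did not pass (adjusted p = 0.090, 0.409, 0.446 and 0.556). PSMB7 had a much dimmer probe set called lower at −1.05, with a mean level of 4.00 against 11.9 for the brighter one. PSMC4 did not pass without empty vector replicate 2 or 3 or USP48 overexpression replicate 1 or 2 (adjusted p = 0.087 without empty vector replicate 3). In the hypoxia response list, 10 of 24 genes rose and 1 fell (12 and 3 adjusted over the list alone; median 0.19, camera adjusted p = 0.0494, adjusted p = 0.31 with an estimated correlation), led by STC2, ANGPTL4 at 2.19, ADM at 1.07 and VEGFA at 1.04. Its median was −0.11 after scaling on the hybridization controls, and the call was lost without empty vector replicate 2 (adjusted p = 0.051), empty vector replicate 3 (adjusted p = 0.089) or USP48 overexpression replicate 3 (adjusted p = 0.196). It was also lost with the mean of all probe sets (adjusted p = 0.126), on ranks (adjusted p = 0.136) and without the dimmest 33.3% of genes (adjusted p = 0.0503).

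No shift was called for the remaining 22 lists, among them the leukocyte and histone lists described above, and several held members that moved both ways. Directions here are those of the USP48-labelled arrays, in which USP48 was not called higher. Of 23 p53 targets 9 rose and 6 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.342), with GADD45A at 2.29, GDF15 at 1.82, SESN2 at 1.40 and ZMAT3 at −1.79. Of 17 genes of the matrix metalloproteinase and plasminogen list 7 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.089), with MMP13 at 1.27, PLAUR at 1.23, PLAU at 0.82 and MMP7 at −0.81. Both lists passed after scaling on the hybridization controls (camera adjusted p = 0.0161 and 0.0182), with the test still directed upward relative to the other genes. Their medians turned from 0.09 to −0.20 and from 0.16 to −0.13, since that scaling lowers every gene alike. Of 17 TGF-β targets 5 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.388), with CCN2, ANGPTL4, TSC22D1 at 1.22 and TGFB2 at 1.21. Of 18 mesenchymal markers 5 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.453), with SNAI2 at 1.74, FN1 at 1.48, ITGA5 at 1.39 and FOXC2 at 0.82. Of 22 epithelial markers 2 rose and 7 fell (3 and 8 adjusted over the list alone; adjusted p = 0.33), with CLDN1 at 1.69, OCLN at −0.72, CLDN7 at −0.59 and ST14 at −0.52. OCLN did not pass with the mean of its probe sets (adjusted p = 0.086). Their median was 0.01, with a mean of −0.04 and a test directed downward. Of 30 extracellular matrix genes 5 rose and 8 fell (5 and 9 adjusted over the list alone; adjusted p = 0.163), with THBS1 at 1.12, FBN2 at −0.95, LOXL1 at −0.90 and COL12A1 at −0.76.

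Metabolic and stress lists without a call included glycolysis, in which 3 of 22 genes rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.335), with SLC2A3 at 1.16, HK2 at 1.07, GPI at −0.40 and PFKFB3 at 0.24. PFKFB3 was at −0.05 after scaling on the hybridization controls and did not pass without any 1 of the 6 arrays (adjusted p = 0.122 without empty vector replicate 1). GPI did not pass without empty vector replicate 1 (adjusted p = 0.073) or 2 or USP48 overexpression replicate 3. Of 17 genes of the ER unfolded protein response 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.226), with HERPUD1 at 0.71, XBP1 at 0.70, DNAJB9 at 0.63 and the chaperone HSPA5 at 0.58. A dimmer XBP1 probe set was called lower at −0.58, and XBP1 did not pass with the mean of its probe sets (0.06, adjusted p = 0.613). HSPA5 did not pass after scaling on the hybridization controls (adjusted p = 0.069). Of 22 lysosome and autophagy genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.298), with GABARAPL1 at 1.24, MAP1LC3B at 0.61, CTSL at 0.56 and NEU1 at 0.47. CTSL and NEU1 did not pass after scaling on the hybridization controls (0.27 and 0.18, adjusted p = 0.090 and 0.283). Of 19 NRF2 targets 3 rose and 4 fell (4 and 5 adjusted over the list alone; adjusted p = 0.98; median 0.03, test directed downward), with AKR1B10 at 0.88, AKR1C3 at −0.69, GCLM at 0.65 and TKT at −0.52. GCLM did not pass with the mean of its probe sets (adjusted p = 0.172). Of 24 ferroptosis regulators 6 rose and 5 fell (6 and 6 adjusted over the list alone; adjusted p = 0.606), with CHAC1, PTGS2 at 2.20, STEAP3 at −1.14 and SAT1 at 1.11. None of 28 cytosolic ribosomal protein genes passed (0 and 0 adjusted over the list alone; camera adjusted p = 0.453), and RPLP2 and RPL3 were at 0.21 and −0.15. After scaling on the hybridization controls 20 of the ribosomal genes were lower, RPL3 among them, and the medians of the unfolded protein response, lysosome, NRF2 and ferroptosis lists were −0.16, −0.14, −0.26 and −0.26, against 0.13, 0.15, 0.03 and 0.03 as deposited. USP48 was not called higher in the arrays these directions refer to.

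Other ubiquitin-specific proteases moved in both directions in the USP48-labelled arrays, in which USP48 was not called higher. Of 41 such genes 9 rose and 8 fell (11 and 9 adjusted over the list alone; camera adjusted p = 0.515). USP18, an interferon-induced protease, was at 2.07, USP7 at −1.86, USP34 at −1.38 and USP22 at −1.31. A much dimmer USP22 probe set, with a mean level of 1.94, was called higher at 0.32. A list of reported USP48 substrates was fixed before the data were examined, and the standing of its members as substrates was not checked here. Of its 8 measured genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.991), with BRCA1 at −0.60, FTO at −0.50, RELA at 0.35 and SIRT6 at 0.27. The arrays measure RNA, so these values say nothing of the protein levels of substrates. RELA and SIRT6 did not pass after scaling on the hybridization controls (0.06 and −0.02, adjusted p = 0.672 and 0.878), which left 0 of the 8 called higher. SIRT6 also did not pass without any 1 of the 5 arrays other than USP48 overexpression replicate 3 (adjusted p = 0.144 without USP48 overexpression replicate 2). In the Hedgehog list 0 of 13 genes rose and 3 fell (0 and 3 adjusted over the list alone; adjusted p = 0.331), PTCH1 at −0.52, GLI2 at −0.48 and SUFU at −0.42. PTCH1 and SUFU did not pass with the mean of their probe sets (adjusted p = 0.081 and 0.391). Of 15 Wnt/β-catenin targets 2 rose and 2 fell (2 and 1 adjusted over the list alone; adjusted p = 0.906), MYC at 0.71, CCND1 at 0.53, ZNRF3 at −0.42 and SP5 at −0.31. CCND1 did not pass after scaling on the hybridization controls (0.24, adjusted p = 0.213). SP5 did not pass without any 1 of the 5 arrays other than empty vector replicate 3 (adjusted p = 0.179 without empty vector replicate 2).

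Markers of cell types gave no called shift. Of 25 hepatocyte markers 2 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.453): the urea cycle enzyme CPS1 at −1.41, ASGR1 at 0.39 and TAT at 0.33. ASGR1 did not pass without USP48 overexpression replicate 2 (adjusted p = 0.095) or empty vector replicate 3. TAT did not pass without empty vector replicate 1 (adjusted p = 0.074) or with the mean of its probe sets (adjusted p = 0.114). Neither passed after quantile normalization (adjusted p = 0.086 and 0.065) or after scaling on the hybridization controls (0.10 and 0.03, adjusted p = 0.530 and 0.813). Of 16 progenitor and stem cell markers 5 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.453), KLF4 at 1.67, ALDH1A3 at −1.33, CD24 at 1.28 and NES at −1.15. Of 13 fibroblast and stellate cell markers 0 rose and 2 fell (0 and 2 adjusted over the list alone; adjusted p = 0.298), LUM at −1.35 and DCN at −1.14. Of 12 endothelial markers 0 rose and 1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.792), CDH5 at −0.42, which did not pass without empty vector replicate 2 (adjusted p = 0.059). These directions are those of the USP48-labelled arrays, in which USP48 was not called higher. After scaling on the hybridization controls the medians of the hepatocyte, progenitor and endothelial lists were −0.17, −0.14 and −0.22, against 0.12, 0.15 and 0.07 as deposited.

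**Figure D3:**
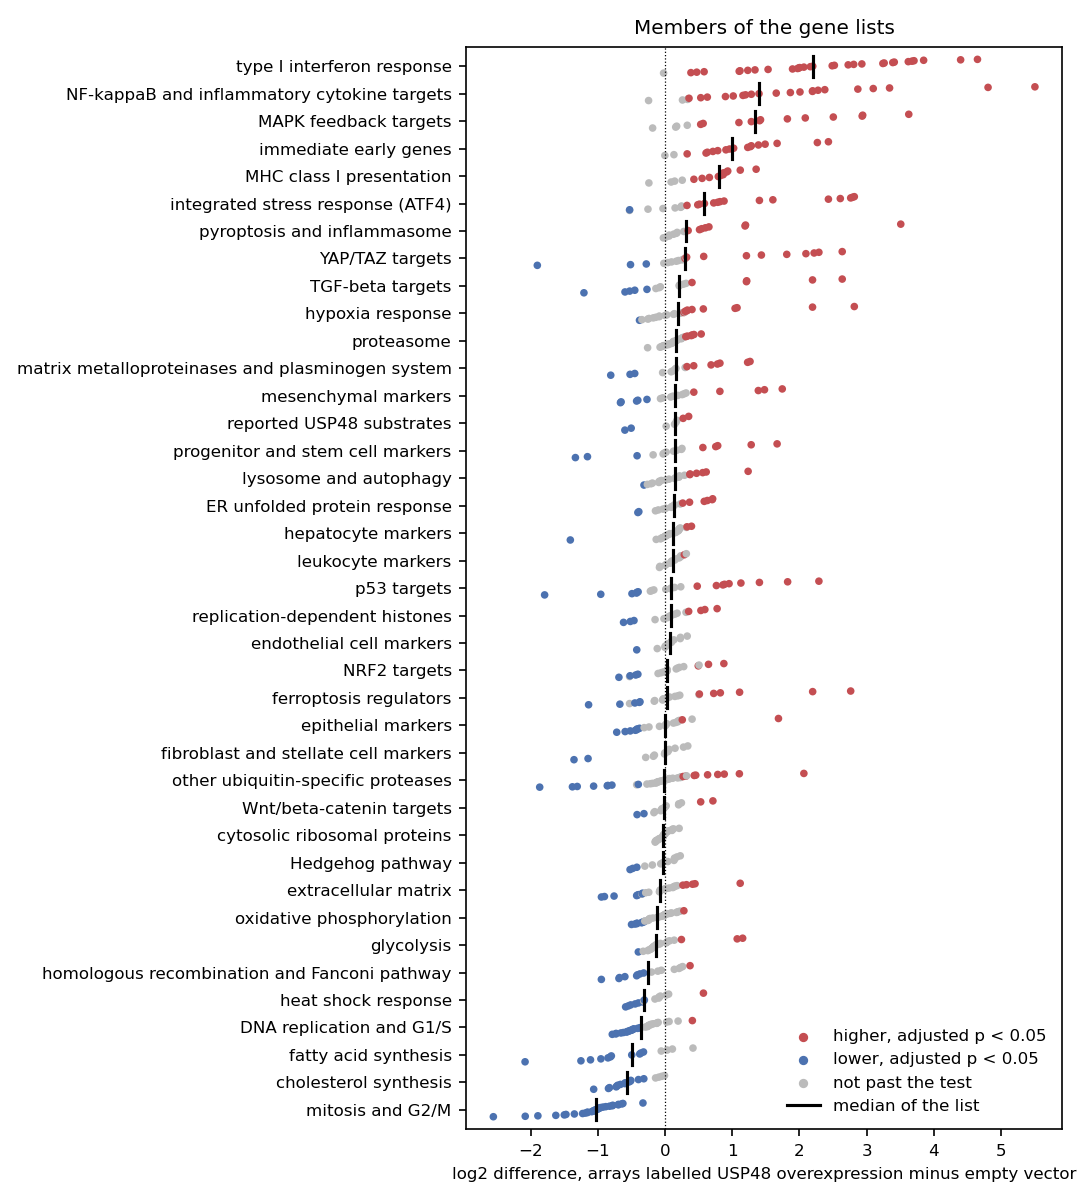
Log2 difference (x axis, arrays labelled USP48 overexpression minus empty vector, 3 arrays each) of every measured member of the 39 gene lists (y axis), each point 1 gene, coloured by direction where its limma adjusted p is under 0.05, with the median of each list as a black line. The interferon list lies highest with a median of 2.20 and the mitosis list lowest with −1.03. USP48 was not called higher in the arrays so labelled, and scaling on the hybridization controls turns the sign of several medians near 0.

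Of the 39 lists, 17 were called, 10 higher and 7 lower, and 0 were called by camera with an estimated correlation, where 7 had an unadjusted p under 0.05. The estimates ranged widely among the called lists, such as 0.65 for interferon, 0.003 for YAP/TAZ and −0.02 for immediate early genes. The last 2 lie below the preset 0.01, yet their camera adjusted p rose to 0.173 and 0.064. A lost call therefore does not by itself show correlation among the members.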

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

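Groups of 3 arrays were not tested for outlying arrays, and the design holds 1 contrast. The tests of control probe sets, of probe sets that name no single gene and of other splits were chosen after the results were seen. A signal outside the measured genes was found in 3 places. Among 13522 probe sets that name no single gene, 2435 changed at a limma adjusted p under 0.05, 799 higher and 1636 lower in the arrays labelled USP48 overexpression.

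The hybridization controls differed by 0.294 and the poly-A controls by 0.418 on the log2 scale, both higher in the arrays labelled USP48 overexpression. The exact permutation p was 0.1 for each, the smallest that 3 against 3 arrays allow, and 17 of the 24 poly-A control probe sets were higher in every USP48-labelled array.

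Only the real grouping of the 10 splits of the 6 arrays into 3 and 3 gave as many changed genes (1 of 10 splits; 5897 genes, highest other split 0), as many genes changed at least 2-fold (1 of 10; 739, highest other 0) and as many called lists (1 of 10; 17, highest other 13). With 10 splits no share under 0.05 can be reached. Each other split mixed the groups, which adds their difference to the spread, so the contrast with 0 genes says little. The other splits still called 7 to 13 lists, with 0 genes changed. In each of them the arrays of a group were divided unevenly, so part of the group difference stayed in the contrast. The 7 to 13 lists are therefore not a rate of false calls.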

How the results depend on the processing

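Scaling on the hybridization controls was chosen after seeing the data, and the other alternatives before. With each array left out in turn, 4547 to 5673 genes changed, 701 to 809 at least 2-fold, 15 to 17 lists were called, and USP48 lay between −0.18 and −0.09. The replicate numbers do not pair the samples: same-numbered arrays' deviations from the group means correlated at 0.004, 0.166 and 0.015. With the replicate block 5824 genes changed, 739 at least 2-fold, 16 lists were called and USP48 was at −0.13, and hypoxia was the list lost. USP48 passed the threshold at −0.317 with the mean of all probe sets and at −0.422 with the hybridization control scaling. Counts moved by more than 1.5 times with the mean of all probe sets (427 genes at least 2-fold), with every probe set on its own (13287 probe sets changed, 1948 at least 2-fold), with an adjusted p under 0.01 (3847 genes) and with a limit of 1.5-fold (2210 genes). The last 3 follow from counting probe sets or moving the threshold, and for the others the cause was not tested. With an estimated correlation camera called 0 lists. PSMB7 turned to −0.26 with the mean of all probe sets, where a much dimmer probe set was lower. PFKFB3, SIRT6 and CD2 turned to −0.0492, −0.0239 and −0.00621 with the hybridization control scaling, which lowers every gene alike. Of the checks of the 153 named genes other than USP48, 1915 kept direction and side of the threshold, 76 lost the call, 2 gained it and 4 reversed, and 122 of the 153 kept both in every alternative run. For single lists the numbers were 549, 34, 2 and 0. A further 14 sign changes concerned values past no threshold and are counted as kept. Signal over background was not analysed here, which limits what can be said of dim probe sets.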

Other observations

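The families and their tests, the tests of explanations, the probe set and mitosis comparisons and the scaling on the hybridization controls were chosen after the results were seen, while leaving out each array was planned. Among all genes, 15.7% were called higher and 14.1% lower as deposited. Of 9 gene families, with 18 Fisher's exact tests adjusted together, 5 of 6 guanylate-binding proteins, interferon-induced GTPases, were higher in the arrays labelled USP48 overexpression (adjusted p = 0.0030), with GBP1 at 2.71, GBP3 at 1.99 and GBP5 at 1.49 on the log2 scale, and 3 of 6 were higher with arrays scaled on the hybridization controls. Of 22 dual-specificity phosphatases 9 were higher and 1 lower (adjusted p = 0.0145; DUSP4 at 2.09, DUSP10 at 1.77), and after that scaling 5 were higher and 3 lower and their median turned from 0.25 to −0.04. Of 7 death ligands and receptors 4 were higher (adjusted p = 0.0365), TNFSF10 with TNFRSF10A at 1.28, FAS at 0.95 and TNFRSF10B at 0.86, with 4 higher and 1 lower after the scaling. Among 18 interferon genes 3 were higher, IFNB1 at 3.01, IFNL1 at 0.69 and IFNL2 at 0.56, which is no enrichment (adjusted p = 0.80), and 1 was higher and 2 were lower after that scaling. These 3 genes had empty vector means of 2.51, 3.16 and 2.26, GBP5 of 3.25 and TNFSF10 of 2.14. All of these lay below the median of every array. In the USP48-labelled arrays the means were 5.52, 3.84 and 2.82, with GBP5 at 4.74 and TNFSF10 at 5.74. Of those, only IFNL2 at 2.82 lay below it. Detection was not analysed here, so these are differences of RMA values, and whether the transcripts were detected was not tested. Chemokine ligands held 9 higher and 0 lower of 36 (adjusted p = 0.33 for the higher and 0.0210 for the few lower), with 8 higher and 7 lower after the scaling. Many of them had empty vector means below the median of every array, such as CXCL13 at 0.99 and CCL23 at 1.35. Such genes have little room to fall, so the p for the few lower is not a result about the family.

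Lower in the same arrays were 6 of 7 SMC proteins, ATPases that organise chromosomes (adjusted p = 0.00044; SMC4 at −1.47, SMC5 at −0.93, SMC2 at −0.90), 16 of 38 kinesins against 3 higher (adjusted p = 0.00044; KIF1C at −1.59, KIF11 at −1.47, KIF14 at −1.44) and 5 of 8 cullins, scaffolds of ubiquitin ligases (adjusted p = 0.0097; CUL3 at −2.10, CUL5 at −1.83). Several kinesins are also members of the mitosis list. Fisher's exact test treats the genes as independent, and the families were chosen after the results were seen. The p-values of all families therefore describe the pattern and do not test it. The 55 TRIM genes held 12 higher and 9 lower, with no enrichment (adjusted p = 0.36 and 0.70). After scaling on the hybridization controls 7 SMC genes, 20 kinesins, 6 cullins and 22 TRIM genes were lower. That scaling put 7495 of all 19775 genes lower and 957 higher, so the scaled counts of every family hold this general shift. USP48 was not called higher in the arrays from which all these directions are drawn.

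USP48 was not called higher in the arrays labelled USP48 overexpression. Scaling between the arrays that hides a rise would leave the hybridization controls lower in those arrays, and this is argued against by controls 0.294 higher, which put the highest USP48 probe set at −0.052, if every array received the same amount of controls. Whether the probe sets lie outside the transferred sequence cannot be told, because their positions were not analysed here, and the highest of the 5 probe sets was at 0.241. An exchange of the group labels cannot be told apart either: the lowest probe set was at −0.822, short of the fall by more than 1 that was looked for, but probe sets outside the transferred sequence would not fall under an exchange. The transgene itself stays untested, and a biological fall of the cells' own transcript is a further open explanation.

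Interferon and inflammatory lists were higher in the arrays labelled USP48 overexpression. RNA of leukocytes is argued against, because the leukocyte markers other than CD74 and HLA-DRA had a median of 0.125 against 2.20 for the interferon list, and LYZ and PTPRC lay at 2.02 and 1.88. A uniform offset as large as the control difference of 0.294 is too small to account for the rise, since it leaves an interferon median of 1.904. That scaling lowers every gene alike, so it cannot test uneven scaling between the arrays, which stays open. USP48 overexpression replicate 3, the 1 array with a low 5′ signal of GAPDH, is argued against as the whole cause by a median of 2.37 without it. The ACTB 5′ minus 3′ difference lay between −4.14 and −3.26 over all arrays of both groups. Leaving out 1 array therefore does not remove low 5′ signal. Also open are USP48 itself and any difference in RNA integrity. A difference between the lentiviral preparations, culture or selection of the cells is open too. The same holds for the handling of the arrays, whose control probe sets differed between the groups. The design cannot separate any of these from the label. The labelled treatment may account for the rise, as a hypothesis, but USP48 as the cause was not tested.

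Probe sets of one gene often parted. Of 369 genes with at least 2 probe sets above the median gene level of 4.92 and 1 of them at least 2-fold lower, 194 (52.6%) had another above −0.25, against 48 of 174 (27.6%) with a 2-fold higher probe set and another below 0.25. Dim probe sets as the whole cause are argued against, though they matter: the shares were 76.2% with all probe sets, 42.6% above a level of 6 and 37.5% above 7. USP48 overexpression replicate 3, the 1 array with a low 5′ signal of GAPDH, is argued against as the whole cause by 232 such genes without it. However, the GAPDH 5′ to 3′ difference was lower in all 3 USP48-labelled arrays, and the 5′ signal of ACTB was low in every array. A difference in RNA integrity between the groups therefore stays open. Whether parting is as common among genes that rose cannot be told: the excess on the lower side held at the median level (Fisher's exact p = 4.0e-08; after scaling on the hybridization controls 31.5% against 15.1%, p = 0.0012) and above 6 (p = 0.011), but above 7 the shares were 37.5% and 26.4% (p = 0.19), and transcript ends or cross-hybridization may contribute, which needs the positions of the probe sets.

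Tests of the mitosis list were also run and are given as values: its median was −1.327 after scaling on the hybridization controls and −1.026 without USP48 overexpression replicate 3, and its mean lay 0.783 below that of the replication list (difference −0.783, permutation over 31 and 31 genes, p = 1e-05, the smallest that 100000 resamples can give; genes are not independent).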
